A study of Mus musculus with 25 samples.

How the data were processed

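Per the submitters' processing notes, the authors aligned reads to GRCm38 with STAR, counted them to genes with HTSeq and used edgeR and limma, and libraries were made with the Ovation RNA-seq V2 and NEBNext Ultra kits. Tool versions, the role of edgeR and limma, the annotation release and the strand setting are not given in the sources used here. Neither are the inhibitors' identities and doses or the harvest day of the treated cells. The labels' protocols give day 2 in vitro for addition of the inhibitors. The deposited table holds RPKM for 54429 entries in 25 libraries, all of them used.

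Symbols were matched to GENCODE M21 for 53643 entries (98.6%), and 786 did not match, among them Ctgf. The table has 26 symbols turned into spreadsheet dates and 4 entries with a repeated symbol. RPKM times the whole gene span added up to 999076 to 1002560 per library, against 377046 to 519420 with exon length, so the span was taken as the length used. Reads recovered in this way were whole numbers for 99.0 to 99.3% of low values (up to 20 reads, within 0.1 of a whole number). No library pair was identical, and the highest correlation between libraries was 0.971.

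Genes with an RPKM of at least 1 in at least 2 libraries were tested (13850). Each of the 9 groups had its own mean in a single limma fit of log2(RPKM + 1) over the 25 libraries, with 16 residual degrees of freedom and trend and robust empirical Bayes. P-values were adjusted by Benjamini and Hochberg within each comparison and called below 0.05. The 6 comparisons were EGFR inhibitor against DMSO, HBEGF withdrawal against HBEGF, P53 inhibitor against its own DMSO, and days 14 against 2, 7 against 2 and 14 against 7. The difference between the EGFR inhibitor and withdrawal changes was also tested. All p-values in the text are from limma or its camera test, and values after a first adjusted p in a sentence are adjusted too. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

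Gene groups were 32 lists written before the values were seen, from general knowledge of astrocyte state, pathways and cell types. With at least 5 tested members, 29 were tested by camera (preset correlation 0.01), adjusted over the lists of a comparison. Lists for endothelial, ependymal or choroid and erythrocyte genes had too few. Genes rising or falling from day 2 to day 14 by at least 1 in log2 were tested by camera in the treatments, adjusted over 6 tests. Overlaps of calls are given beside the number if calls were independent.

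Genes were named by a rule fixed in advance: up to 8 per direction with the largest log2 change among called genes with a mean of at least 5 RPKM in the higher group and no overlap between libraries, up to 4 members of each list by p, and 8 genes set in advance (Egfr, Hbegf, Trp53, Cdkn1a, Mdm2, Gfap, Aqp4, Mki67). Predicted, clone and pseudogene symbols were left out of the first part. Not all list members picked are printed. The result for 1 of them is not reported here. Folds are ratios of mean RPKM and are given only where the lower group had more than 3 reads.

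Alternatives planned beforehand were a pseudocount of 0.1, no filter, a filter of 5 RPKM, median-of-ratios scaling, quantile normalization, each experiment fitted alone, a replicate block, plain empirical Bayes, array weights, estimated correlation, fry and leaving out each library in turn. Added after the data were seen were log2(CPM + 1), voom on recovered reads and scaling without mitochondrial genes. Lists of the steps from day 2 to 7 and 7 to 14 were put through all settings only after their results were seen.

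The code was tested on simulated data with 13850 genes, 200 of them changed, for each comparison. In the order above, changes of 2-fold were recovered for 71, 58, 60, 70, 69 and 66% of genes and of 4-fold for 93, 88, 90, 90, 90 and 92%. False calls were 4.65, 5.19, 6.83, 11.1, 6.47 and 7.06% of calls. They need not hold here, as library spread differed (array weights 0.406 to 2.56).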

Results

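RNA was measured by sequencing in mouse cortical astrocytes purified by immunopanning with an antibody to HepaCAM and grown in culture. The 25 libraries form 9 groups. Cells given an EGFR inhibitor, or DMSO as its control, gave 3 libraries each, as did cells given a P53 inhibitor and their own DMSO control. Cells grown with HBEGF and cells from which HBEGF was withdrawn gave 2 libraries each, and cells sampled on days 2, 7 and 14 in vitro gave 3 libraries per day. Between 4009173 and 9690782 reads per library were counted to genes (median 6106936), and 8903 to 9865 genes per library had an RPKM of at least 1. Values below are mean RPKM ± SD over the libraries of a group, with treatment, withdrawal or the later day first, and log2 changes are given ± SE. Gene identifiers and positions follow GRCm38 and GENCODE M21.

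The tests compared 13850 genes by limma on log2(RPKM + 1), a scale that understates the fold of genes with low values. The origin of the replicates (animals, cultures or repeated preparations) is not stated, so the p-values measure only the spread between these samples, which may be technical. Named genes were picked by a rule set before the values were seen, except where a sentence says otherwise. Genes that overlap a neighbour or have close copies are uncertain, because the strand setting of the counting is not given in the sources used here. Among genes named below this concerns Miat, Ccnd1, Spry1, Entpd2, Rpph1, Cdkn1c, Sox4, Mt2, Gng3, Tril, Phlda1, P2ry1 and Hmga1b.

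Ribosomal RNA of the mitochondrion took 12.3 to 29.8% of the counted reads. Its share was 23.4 ± 1.77% with the EGFR inhibitor against 18.7 ± 0.237% with DMSO, and 28.9 ± 1.31% after HBEGF withdrawal against 17.7 ± 0.732% with HBEGF. With the P53 inhibitor it was 24.7 ± 1.15% against 23.7 ± 1.01%. On days 2, 7 and 14 it was 14.5 ± 1.99%, 19.2 ± 0.249% and 21.8 ± 1.91%. A larger share for these transcripts leaves a smaller one for all other genes. Among 2354 genes with a mean of at least 5 RPKM, median-of-ratios scaling moved the median log2 change from -0.45 to -0.18 after HBEGF withdrawal and from -0.20 to -0.02 between days 2 and 14. Changes smaller than these shifts depend on the scaling.

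**Figure D1:**
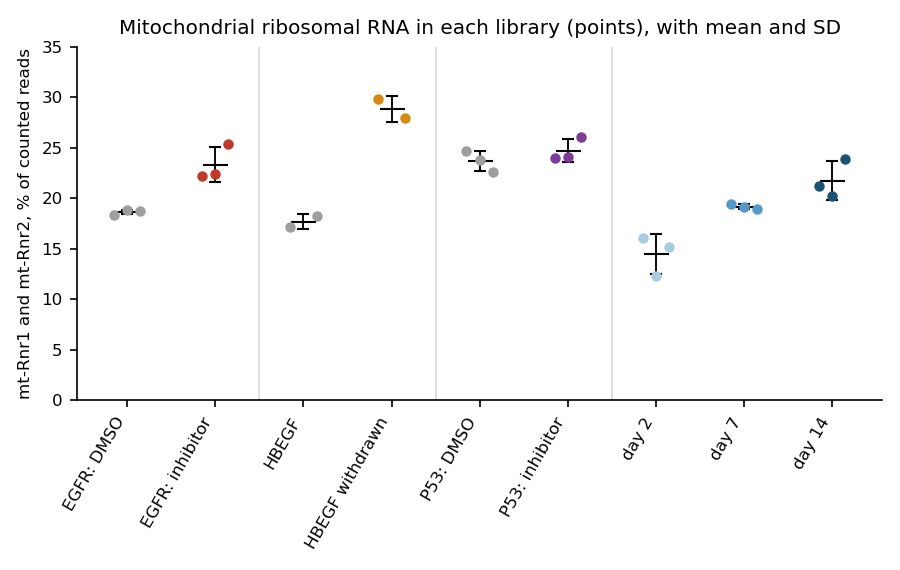
Share of counted reads from mitochondrial ribosomal RNA in each library. Group means ran from 14.5 ± 1.99% on day 2 (n = 3) to 28.9 ± 1.31% after HBEGF withdrawal (n = 2).

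The first comparison asked which genes differ when astrocytes are grown with an EGFR inhibitor (n = 3) instead of DMSO (n = 3). Gfap, which encodes the intermediate filament protein of astrocytes, rose 19-fold, from 3.48 ± 0.324 to 66.05 ± 4.78 RPKM (log2 change 3.90 ± 0.38, adjusted p = 5.64e-07; ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912). Ccnd1, which encodes the cyclin that drives entry into S phase, fell 38.8-fold, from 71.6 ± 16.5 to 1.85 ± 0.513 RPKM (log2 change -4.66 ± 0.27, adjusted p = 2.57e-09; ENSMUSG00000070348.5, chromosome 7, 144929931 to 144939925). All 25 tested cholesterol synthesis genes and all 39 mitosis genes fell, while 19 of 34 genes of mature astrocytes and 16 of 17 tested motile cilium genes, from a list of 61, rose. By limma 5337 of 13850 genes changed, 2261 higher and 3076 lower, and of these 541 and 694 differed by at least 1 in log2. Median-of-ratios scaling gave 2971 higher and 2457 lower, and voom gave 4486 and 4098.

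Homeobox genes of interneuron development were among the largest increases. Dlx1 (ENSMUSG00000041911.3, chromosome 2, 71528113 to 71533981) rose 108-fold to 19.4 ± 1.15 RPKM from 0.180 ± 0.0736 (log2 change 4.11 ± 0.50, adjusted p = 6.16e-06). Its neighbour Dlx2 (ENSMUSG00000023391.8, 71543408 to 71546754) rose to 13.6 ± 1.18 from 0.0864 ± 0.0499 (3.74 ± 0.37, adjusted p = 5.92e-07). Also higher were the noncoding RNA Miat (30 ± 0.834 against 1.89 ± 0.262, adjusted p = 2.26e-09) and the zinc finger gene Insm1 (22.1 ± 1.7 against 1.25 ± 0.439, adjusted p = 1.64e-08). The matricellular gene Ctgf (17.9 ± 4.04 against 1.09 ± 0.583, adjusted p = 1.99e-06) and Cyp1b1 (20.2 ± 2.67 against 1.36 ± 0.161, adjusted p = 2.21e-07) rose. Mirlet7c-1 rose as well (22.1 ± 5.21 against 3.27 ± 4.57, adjusted p = 0.0121), on few reads, and did not pass without EGFR_DMSO replicate 2 (adjusted p = 0.0754). The largest decreases besides Ccnd1 were Igfbp3 (1.56 ± 0.371 against 38.3 ± 6.77, adjusted p = 2.27e-08) and the ERK phosphatase gene Dusp6 (1.57 ± 0.257 against 25.5 ± 8.81, adjusted p = 3.65e-07). Rasl11a (0.836 ± 0.566 against 16 ± 9.28, adjusted p = 1.11e-06) and Inka2 (3.41 ± 0.548 against 37 ± 3.61, adjusted p = 1.23e-09) fell. So did the ERK inhibitor gene Spry1 (0.501 ± 0.0162 against 11.6 ± 0.731, adjusted p = 1.71e-07) and the galectin gene Lgals1 (4.05 ± 0.818 against 39 ± 1.85, adjusted p = 1.48e-07). Snord37 fell from 8.79 ± 5.95 and was listed at 0 in all 3 inhibitor libraries (adjusted p = 0.00121).

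**Figure D2:**
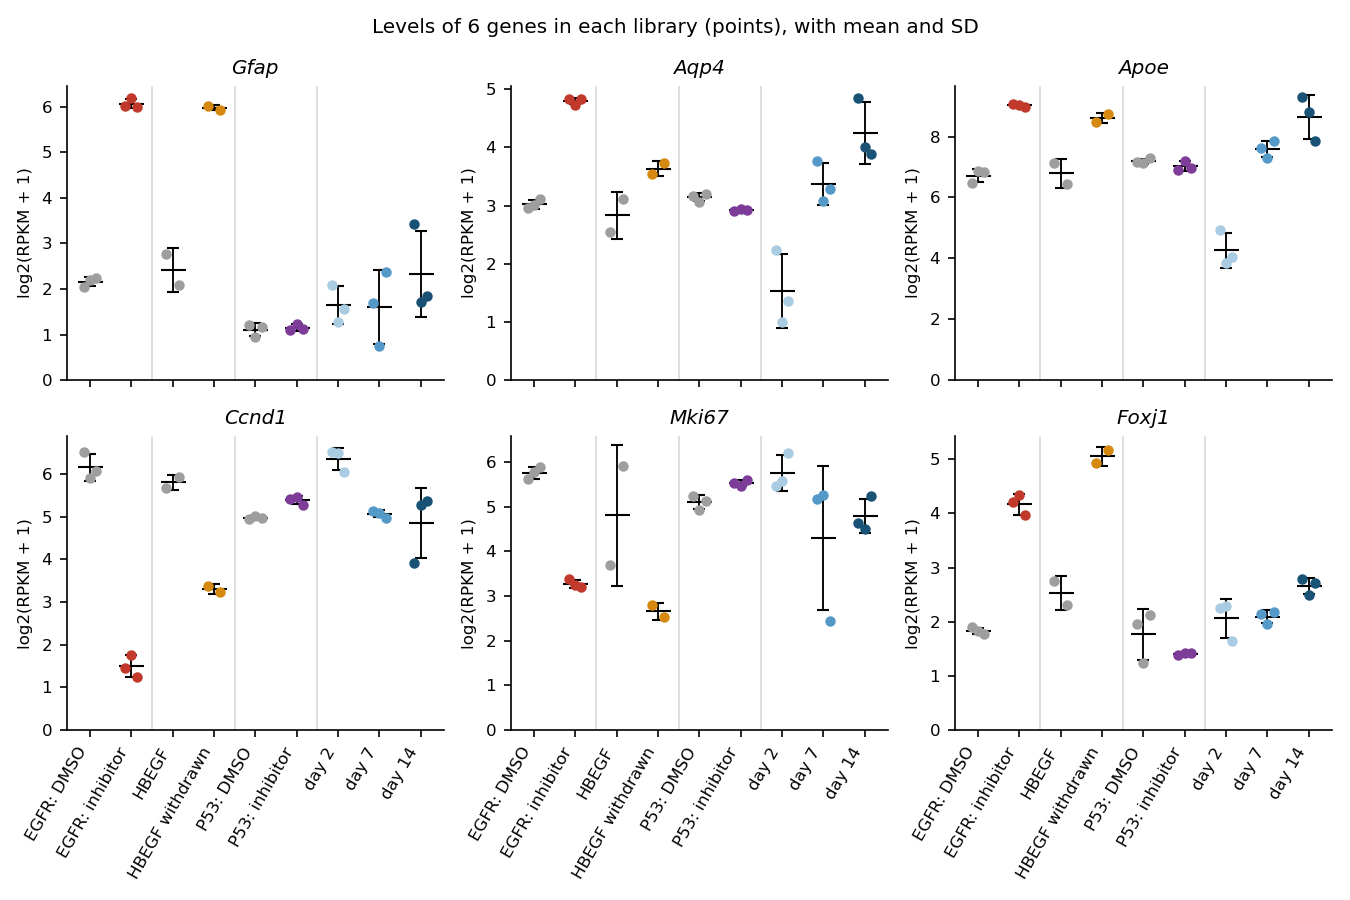
Levels of 6 genes in each library as log2(RPKM + 1), with mean and SD. Gfap was at 66.05 ± 4.78 RPKM with the EGFR inhibitor and 3.48 ± 0.324 with its DMSO control (n = 3 each), and 61.8 ± 2.37 after HBEGF withdrawal and 4.52 ± 1.82 with HBEGF (n = 2 each).

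Genes of mature astrocytes stood at 19 higher and 4 lower of 34 (22 and 7 adjusted over the list alone), with a median log2 change of 0.72 (camera adjusted p = 7.86e-06, or adjusted p = 0.419 with an estimated correlation). The ectonucleotidase gene Entpd2 (5.12 ± 0.258 against 0.282 ± 0.0439, adjusted p = 1.23e-09) and the transcription factor gene Sox9 (121 ± 7.23 against 41.7 ± 7.15, adjusted p = 1.22e-06) rose. The gap junction gene Gja1 (19.9 ± 1.83 against 4.19 ± 0.393, adjusted p = 1.73e-06) rose too, as did Mlc1 (12.8 ± 1.0 against 5.74 ± 0.241, adjusted p = 2.17e-06) and the water channel gene Aqp4 (26.9 ± 1.07 against 7.13 ± 0.44, log2 change 1.78 ± 0.27, adjusted p = 4.44e-05, ENSMUSG00000024411.10, chromosome 18, 15389496 to 15410982). Radial glia genes went both ways, with 12 higher and 9 lower of 28 (13 and 10 adjusted over the list alone, camera adjusted p = 0.463), and passed as higher under quantile normalization (0.043). Within them Igfbp5 (31.6 ± 2.14 against 4.61 ± 0.504, adjusted p = 6.41e-09) and Pax6 (4.37 ± 0.0772 against 1.7 ± 0.203, adjusted p = 4.07e-08) rose, and Fbln2 (0.782 ± 0.133 against 11.8 ± 1.01, adjusted p = 7.44e-08) and the fatty acid binding gene Fabp7 (359 ± 8.49 against 1094 ± 98, adjusted p = 1.87e-07) fell. Astrocyte genes that regulate synapses gave 11 higher and 5 lower of 22 (12 and 6 adjusted over the list alone, camera adjusted p = 0.0275, or adjusted p = 0.272 with an estimated correlation), a call lost with no filter (adjusted p = 0.0765), a filter of 5 RPKM (0.132), log2(CPM + 1) (0.161) and voom (0.137). The complement gene C4b (3.87 ± 0.515 against 0.124 ± 0.0476, adjusted p = 3.3e-07) and Thbs1 (3.7 ± 0.721 against 0.424 ± 0.225, adjusted p = 9.91e-06) rose and Nptx2 (0.451 ± 0.177 against 2.04 ± 0.20, adjusted p = 1.19e-05) fell. Reactive astrocyte genes gave 8 higher and 4 lower of 17 (8 and 5 adjusted over the list alone, camera adjusted p = 0.176), and passed with a filter of 5 RPKM (0.0445). S1pr3 (5.9 ± 1.3 against 0.944 ± 0.397, adjusted p = 2.64e-05) and Osmr (0.886 ± 0.0609 against 0.0537 ± 0.00812, adjusted p = 3.08e-05) rose and Cd44 (0.434 ± 0.0382 against 1.75 ± 0.118, adjusted p = 4.86e-06) fell.

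Genes of cell division fell as a group. The mitosis list stood at 0 higher and 39 lower of 39 (0 and 39 adjusted over the list alone), median -1.78 (camera adjusted p = 1.55e-13, or adjusted p = 0.394 with an estimated correlation). The DNA replication list stood at 0 higher and 34 lower of 35 (0 and 34 adjusted over the list alone), median -0.999 (camera adjusted p = 4.66e-14, or adjusted p = 0.272 with an estimated correlation). The proliferation marker Mki67 (8.72 ± 0.615 against 53.3 ± 5.16, log2 change -2.48 ± 0.56, adjusted p = 0.00183) fell. The kinase gene Cdk1 (0.976 ± 0.167 against 8.26 ± 0.309, adjusted p = 4.82e-05) fell too. Targets of ERK feedback stood at 1 higher and 19 lower of 24 (1 and 19 adjusted over the list alone, camera adjusted p = 6.18e-09, or adjusted p = 0.119 with an estimated correlation). The ETS factor gene Etv5 (1.12 ± 0.301 against 4.87 ± 0.104, adjusted p = 1.64e-08) fell. The receptor gene Egfr (3.5 ± 0.113 against 6.55 ± 0.628, log2 change -0.74 ± 0.16, adjusted p = 0.00111) fell (ENSMUSG00000020122.16, chromosome 11, 16752203 to 16918158). The ligand gene Hbegf (0.955 ± 0.315 against 7.11 ± 6.84, log2 change -1.75 ± 0.47, adjusted p = 0.00636) fell with EGFR_DMSO replicate 1 at 15.01 RPKM. Genes of EGF ligands and receptors gave 0 higher and 4 lower of 5 (0 and 4 adjusted over the list alone, camera adjusted p = 0.156), or 1 and 2 under median-of-ratios scaling. P53 targets gave 4 higher and 8 lower of 26 (4 and 8 adjusted over the list alone, camera adjusted p = 0.184). Cdkn1a (7.96 ± 1.06 against 19.8 ± 0.385, log2 change -1.22 ± 0.30, adjusted p = 0.00368) fell and Pltp (0.881 ± 0.183 against 0.187 ± 0.0601, adjusted p = 7.89e-05) rose. Mdm2 (5.22 ± 0.254 against 4.57 ± 0.272, adjusted p = 0.281) did not pass, although median-of-ratios scaling gave adjusted p = 0.0305. Trp53 (6.62 ± 0.934 against 9.18 ± 0.226, log2 change -0.43 ± 0.12, adjusted p = 0.00972) fell, a call lost without EGFR_inhibitor replicate 3 (adjusted p = 0.0610).

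Cholesterol synthesis genes had a median log2 change of -1.53, with 0 higher and 25 lower of 25 (0 and 25 adjusted over the list alone, camera adjusted p = 2.93e-18, or adjusted p = 0.119 with an estimated correlation). The sterol genes Hmgcs1 (5.34 ± 0.868 against 40 ± 5.36, adjusted p = 1.64e-08) and Cyp51 (1.82 ± 0.244 against 17.4 ± 1.79, adjusted p = 3.39e-08) fell. Oxidative phosphorylation genes stood at 0 higher and 25 lower of 41 (0 and 27 adjusted over the list alone, camera adjusted p = 6.77e-07, or adjusted p = 0.419 with an estimated correlation). Ribosomal protein genes stood at 0 higher and 17 lower of 41 (0 and 17 adjusted over the list alone, camera adjusted p = 0.000859, or adjusted p = 0.647 with an estimated correlation), and their list did not pass under quantile normalization (10 lower, adjusted p = 0.0505). Genes of endoplasmic reticulum stress stood at 2 higher and 13 lower of 26 (3 and 13 adjusted over the list alone, camera adjusted p = 0.0245, or adjusted p = 0.652 with an estimated correlation). Glycolysis genes gave 6 higher and 9 lower of 19 (6 and 9 adjusted over the list alone, camera adjusted p = 0.494).

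Motile cilium genes stood at 16 higher and 1 lower of 17 (16 and 1 adjusted over the list alone), median 0.77 (camera adjusted p = 2.37e-11, or adjusted p = 0.0187 with an estimated correlation). The ciliary transcription factor gene Foxj1 (17.1 ± 2.37 against 2.57 ± 0.147, log2 change 2.34 ± 0.20, adjusted p = 1.54e-07) and Tppp3 (5.21 ± 0.903 against 1.2 ± 0.162, adjusted p = 9.1e-08) rose. Intraflagellar transport genes gave 11 higher and 4 lower of 28 (11 and 4 adjusted over the list alone, camera adjusted p = 0.0915), or 13 and 1 under median-of-ratios scaling, where the list passed as higher (0.0409), as it did without mitochondrial genes (0.0324) and with no filter (0.0352). Circadian clock genes gave 8 higher and 2 lower of 18 (8 and 2 adjusted over the list alone, camera adjusted p = 0.00985, or adjusted p = 0.272 with an estimated correlation), a call lost with a filter of 5 RPKM (adjusted p = 0.424), log2(CPM + 1) (0.0921) and voom (0.0864). The immediate early gene Fos (6.22 ± 0.69 against 1.49 ± 0.577, adjusted p = 5.9e-07) rose while Egr1 (20.3 ± 4.25 against 84.3 ± 12.1, adjusted p = 9.38e-06) fell. Their list gave 6 higher and 8 lower of 18 (6 and 8 adjusted over the list alone, camera adjusted p = 0.718). Of genes in BMP and Notch signalling Id4 (35.7 ± 1.31 against 4.27 ± 0.565, adjusted p = 4.42e-07) rose and Hes1 (2.08 ± 0.202 against 4.87 ± 0.618, adjusted p = 1.42e-05) fell. Counts in that list were 6 higher and 4 lower of 13 (6 and 5 adjusted over the list alone, camera adjusted p = 0.516).

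Marker genes of other cell types were measured beside these groups. Neuron genes stood at 8 higher and 2 lower of 11 (9 and 2 adjusted over the list alone, camera adjusted p = 0.000859, or adjusted p = 0.272 with an estimated correlation), with Tubb3 (3.03 ± 0.591 against 0.159 ± 0.0158, adjusted p = 1.63e-05) higher and Dlx5 at 1.95 ± 0.168 RPKM against 0 in all DMSO libraries. Microglia genes stood at 6 higher and 0 lower of 7 (6 and 0 adjusted over the list alone, camera adjusted p = 0.00754, or adjusted p = 0.119 with an estimated correlation), among them Lyz2 (2.54 ± 1.3 against 0.549 ± 0.12, adjusted p = 0.00172). Genes of oligodendrocyte precursors gave 3 higher and 4 lower of 11 (5 and 4 adjusted over the list alone, camera adjusted p = 0.973), or 6 and 4 under median-of-ratios scaling. Olig1 (60.6 ± 4.9 against 248 ± 29.4, adjusted p = 2.37e-08) fell. Oligodendrocyte genes gave 1 higher and 0 lower of 5 (0 and 0 adjusted over the list alone, camera adjusted p = 0.317). Pericyte genes gave 1 higher and 1 lower of 5 (1 and 1 adjusted over the list alone, camera adjusted p = 0.627). Genes on the mitochondrial genome gave 2 higher and 2 lower of 10 (2 and 2 adjusted over the list alone, camera adjusted p = 0.494). Interferon genes gave 2 higher and 1 lower of 10 (2 and 1 adjusted over the list alone, camera adjusted p = 0.840). Matrix genes gave 4 higher and 10 lower of 15 (4 and 10 adjusted over the list alone, camera adjusted p = 0.176). Cytoskeleton genes gave 5 higher and 7 lower of 21 (5 and 7 adjusted over the list alone, camera adjusted p = 0.627) and ion or transmitter transport genes 8 higher and 7 lower of 23 (8 and 8 adjusted over the list alone, camera adjusted p = 0.647). Median, mean and camera direction differed in sign for the radial glia, interferon, cytoskeleton and oligodendrocyte precursor lists.

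The second comparison asked which genes differ after HBEGF withdrawal (n = 2) from cells kept with HBEGF (n = 2). Fabp7, which encodes a fatty acid binding protein of radial glia, fell 9.11-fold, from 1382 ± 191 to 152 ± 17.6 RPKM (log2 change -3.18 ± 0.17, adjusted p = 2.73e-09; ENSMUSG00000019874.11, chromosome 10, 57784881 to 57788450). Gfap rose 13.7-fold, from 4.52 ± 1.82 to 61.8 ± 2.37 RPKM (log2 change 3.55 ± 0.47, adjusted p = 1.79e-05). Of the fixed groups, 34 of 35 DNA replication genes and 20 of 25 cholesterol synthesis genes fell. Of tested motile cilium genes 16 of 17 rose, as did 6 of 7 tested microglia genes, from a list of 24. By limma 4511 genes changed, 1390 higher and 3121 lower, and 455 and 742 of them differed by at least 1 in log2. The split depended on scaling, with 2296 higher and 1798 lower under median-of-ratios scaling, 1698 and 2285 under quantile normalization, and 2027 and 2157 without mitochondrial genes. Fitted without the other groups, 0 genes passed in limma, where 3926 had an unadjusted p under 0.05, so the calls rest on a spread shared with the other 21 libraries.

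Lysozyme gene Lyz2 (16.9 ± 9.29 against 0.082 ± 0.116, adjusted p = 1.54e-07) had the largest increase. Scarna2 (13.8 ± 1.89 against 0.354 ± 0.0601, adjusted p = 6.39e-07) and the imprinted noncoding gene H19 (22 ± 5.95 against 1.56 ± 0.164, adjusted p = 1.06e-05) rose. Cyp1b1 (21 ± 2.33 against 1.57 ± 0.728, adjusted p = 3.55e-06) and the growth factor binding gene Igfbp5 (67.9 ± 12.6 against 7.51 ± 3.43, adjusted p = 1.74e-08) rose as well. Mir6352 rose to 7.45 ± 0.754 RPKM and was listed at 0 with HBEGF (adjusted p = 0.00286). Rpph1 rose (102 ± 49.0 against 7.90 ± 8.26, adjusted p = 0.00465), a call lost without HBEGF replicate 2 (adjusted p = 0.0891). Largest decreases besides Fabp7 were Inka2 (2.02 ± 0.817 against 27.8 ± 1.56, adjusted p = 9.58e-09) and Dusp6 (3.6 ± 0.979 against 37.9 ± 6.21, adjusted p = 9.3e-06). The peptide ligand gene Apln (0.175 ± 0.131 against 8.57 ± 0.848, adjusted p = 0.00062) and Spry1 (0.641 ± 0.302 against 9.86 ± 1.43, adjusted p = 6.92e-06) fell too. Mir703 fell too (adjusted p = 0.00375, 5.66 ± 8.01 against 26.9 ± 12.4), but not without HBEGF_withdrawal replicate 2 (adjusted p = 0.0830). Snora41 and Snord93 fell from 6.56 ± 0.440 and 6.01 ± 1.89 RPKM and were listed at 0 after withdrawal (adjusted p = 8.84e-05 and 0.00565).

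Mature astrocyte genes stood at 16 higher and 5 lower of 34 (19 and 6 adjusted over the list alone), median 0.60 (camera adjusted p = 0.000128, or adjusted p = 0.531 with an estimated correlation). The gene Entpd2 (1.81 ± 0.0263 against 0.163 ± 0.103, adjusted p = 4.6e-06) rose and the bicarbonate transporter gene Slc4a4 (0.425 ± 0.0163 against 2.26 ± 0.192, adjusted p = 1.37e-06) fell. Aqp4 was at 11.4 ± 1.10 against 6.26 ± 2.01 RPKM and did not pass (adjusted p = 0.0691), although it did under median-of-ratios scaling (adjusted p = 0.0196). Reactive astrocyte genes stood at 9 higher and 2 lower of 17 (9 and 2 adjusted over the list alone, camera adjusted p = 0.000124, or adjusted p = 0.216 with an estimated correlation). S1pr3 (16.4 ± 0.919 against 2.2 ± 1.5, adjusted p = 1.26e-05) rose. Radial glia genes gave 8 higher and 12 lower of 28 (8 and 13 adjusted over the list alone, camera adjusted p = 0.612) and a median of -0.38, or 0.0025 under quantile normalization. Within this list Pax6 (4.51 ± 0.037 against 1.46 ± 0.0487, adjusted p = 1.54e-07) rose and Ptprz1 (7.6 ± 0.675 against 21.7 ± 6.11, adjusted p = 1.05e-05) fell. Synapse regulating genes gave 4 higher and 8 lower of 22 (4 and 9 adjusted over the list alone, camera adjusted p = 0.880), or 7 and 4 under median-of-ratios scaling.

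DNA replication genes fell with a median of -1.13 and 0 higher and 34 lower of 35 (0 and 34 adjusted over the list alone, camera adjusted p = 2.82e-14, or adjusted p = 0.261 with an estimated correlation). Mitosis genes stood at 0 higher and 24 lower of 39 (0 and 34 adjusted over the list alone, camera adjusted p = 1.5e-05, or adjusted p = 0.619 with an estimated correlation), and at 0 higher and 15 lower under median-of-ratios scaling. The mitosis call was lost without HBEGF replicate 2 (camera adjusted p = 0.209). Mki67 (5.34 ± 0.813 against 35.8 ± 33.7, log2 change -2.15 ± 0.69, adjusted p = 0.0227) fell, with HBEGF libraries at 11.97 and 59.62 RPKM (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361). That gene did not pass without HBEGF replicate 2 (adjusted p = 0.354), HBEGF_withdrawal replicate 1 (0.0602) or HBEGF_withdrawal replicate 2 (0.103), nor under median-of-ratios scaling (0.0523). Targets of ERK feedback stood at 3 higher and 18 lower of 24 (3 and 19 adjusted over the list alone, camera adjusted p = 0.0001, or adjusted p = 0.261 with an estimated correlation). Lrig1 (0.662 ± 0.146 against 2.24 ± 0.0769, adjusted p = 2.11e-06) fell and Fos (7.76 ± 0.49 against 1.84 ± 0.41, adjusted p = 5.32e-06) rose. Ccnd1 (8.9 ± 0.771 against 55 ± 6.8, log2 change -2.50 ± 0.33, adjusted p = 1.88e-05) fell.

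The receptor gene Egfr (2.03 ± 0.0374 against 4.33 ± 1.04, log2 change -0.80 ± 0.19, adjusted p = 0.00397) fell, a call lost without HBEGF replicate 2 (adjusted p = 0.0706). Its ligand gene Hbegf (2.22 ± 0.917 against 13.2 ± 8.38, log2 change -2.04 ± 0.58, adjusted p = 0.0110) fell, but not without HBEGF replicate 1 (adjusted p = 0.143) or HBEGF_withdrawal replicate 2 (0.0888). Trp53 (6.67 ± 0.231 against 10.7 ± 1.1, log2 change -0.61 ± 0.15, adjusted p = 0.00441) fell, which median-of-ratios scaling did not call (adjusted p = 0.0670), and Cdkn1a (18.7 ± 8.17 against 16.8 ± 6.55, adjusted p = 0.840) did not pass. Mdm2 did not pass either (6.52 ± 0.966 against 5.73 ± 1.37, adjusted p = 0.377), although median-of-ratios scaling gave adjusted p = 0.0124. P53 targets gave 2 higher and 7 lower of 26 (2 and 7 adjusted over the list alone, camera adjusted p = 0.654), or 7 higher and 3 lower under median-of-ratios scaling. Pltp (1.81 ± 0.0427 against 0.224 ± 0.0236, adjusted p = 2.82e-06) rose and Plk2 (2.26 ± 0.575 against 6.47 ± 0.432, adjusted p = 0.00371) fell. Of immediate early genes Dusp1 (14.6 ± 0.532 against 4.87 ± 0.876, adjusted p = 4.23e-05) rose and Egr1 (14.8 ± 2.39 against 73.1 ± 2.27, adjusted p = 3.56e-05) fell.

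Cholesterol synthesis genes stood at 0 higher and 20 lower of 25 (0 and 24 adjusted over the list alone), median -0.99 (camera adjusted p = 5.65e-09, or adjusted p = 0.261 with an estimated correlation). Cyp51 (2.69 ± 1.04 against 14.2 ± 4.68, adjusted p = 7.66e-06) and Hmgcs1 (9.16 ± 2.73 against 30.5 ± 13.8, adjusted p = 4.33e-05) fell. Oxidative phosphorylation genes stood at 0 higher and 21 lower of 41 (0 and 22 adjusted over the list alone, camera adjusted p = 4.13e-05, or adjusted p = 0.531 with an estimated correlation), with a median of -0.42, but 14 lower and a median of -0.16 under median-of-ratios scaling. Ribosomal protein genes stood at 1 higher and 24 lower of 41 (1 and 26 adjusted over the list alone, camera adjusted p = 0.000124, or adjusted p = 0.531 with an estimated correlation), with a median of -0.68, but 13 lower and -0.39 under median-of-ratios scaling. Glycolysis genes gave 6 higher and 6 lower of 19 (6 and 6 adjusted over the list alone, camera adjusted p = 0.799) and a median of -0.13, or 0.127 under median-of-ratios scaling, and Ldha (7.22 ± 0.777 against 28 ± 3.0, adjusted p = 1.3e-06) fell. Stress genes gave 2 higher and 12 lower of 26 (3 and 12 adjusted over the list alone, camera adjusted p = 0.0747), or 4 and 9 under median-of-ratios scaling. Matrix genes gave 4 higher and 6 lower of 15 (4 and 6 adjusted over the list alone, camera adjusted p = 0.348), or 5 and 5 after such scaling and 17 and 8 of 37 with voom, and Bgn (2.95 ± 0.616 against 0.188 ± 0.0589, adjusted p = 2.63e-08) rose. BMP and Notch genes gave 3 higher and 4 lower of 13 (3 and 5 adjusted over the list alone, camera adjusted p = 0.936), or 3 and 2 when scaled so, where Id4 (22.8 ± 3.69 against 4.86 ± 0.701, adjusted p = 0.000132) rose and Id3 (5.3 ± 1.09 against 18.8 ± 0.265, adjusted p = 3e-05) fell.

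Motile cilium genes rose with a median of 1.19 and 16 higher and 1 lower of 17 (16 and 1 adjusted over the list alone, camera adjusted p = 1.16e-18, or adjusted p = 0.00121 with an estimated correlation). The microtubule gene Tppp3 rose 22.4-fold (11.3 ± 0.40 against 0.506 ± 0.141, log2 change 3.04 ± 0.15, adjusted p = 8.87e-10), and Rsph4a (4.54 ± 0.511 against 0.682 ± 0.201, adjusted p = 1.54e-07) rose. Summed CPM of 17 ependymal and choroid genes, among them Foxj1, were 7.22-fold higher after withdrawal and 5.47-fold with the EGFR inhibitor. Intraflagellar transport genes stood at 11 higher and 3 lower of 28 (13 and 4 adjusted over the list alone, camera adjusted p = 0.00352, or adjusted p = 0.105 with an estimated correlation). Circadian clock genes stood at 9 higher and 2 lower of 18 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00172, or adjusted p = 0.202 with an estimated correlation). Per3 (1.65 ± 0.268 against 0.44 ± 0.0519, adjusted p = 0.000261) rose. The other 16 lists were not called by camera (adjusted p from 0.0747 for endoplasmic reticulum stress to 0.936 for BMP and Notch). Several passed elsewhere. With voom these were stress genes as lower (0.0178), oligodendrocyte precursors as lower (0.0246), and interferon (0.00984), matrix (0.00711), neuron (0.0178) and immediate early genes (0.0246) as higher. Stress passed without HBEGF_withdrawal replicate 1 (0.00729) or HBEGF replicate 2 (0.0166), precursors without HBEGF replicate 2 (0.0489), neurons without HBEGF replicate 1 (0.0409), pericytes without HBEGF_withdrawal replicate 1 (0.0422) and immediate early genes without HBEGF replicate 1 (0.0388) or HBEGF_withdrawal replicate 2 (0.05).

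Microglia genes stood at 6 higher and 0 lower of 7 (6 and 0 adjusted over the list alone), median 1.31 (camera adjusted p = 2.78e-07, or adjusted p = 0.00231 with an estimated correlation). Lyz2 (above) and Cd68 (5.57 ± 0.962 against 1.09 ± 0.707, adjusted p = 0.000221) rose. Oligodendrocyte genes stood at 4 higher and 0 lower of 5 (4 and 0 adjusted over the list alone, camera adjusted p = 5.62e-05, or adjusted p = 0.118 with an estimated correlation). The myelin gene Mbp (5.25 ± 0.408 against 1.38 ± 0.891, adjusted p = 9.13e-06) rose. Genes of oligodendrocyte precursors gave 1 higher and 4 lower of 11 (1 and 4 adjusted over the list alone, camera adjusted p = 0.110). Olig1 (49.3 ± 6.99 against 251 ± 10.6, adjusted p = 8.97e-08) fell. Neuron genes gave 3 higher and 0 lower of 11 (3 and 0 adjusted over the list alone, camera adjusted p = 0.159). mt-Rnr1 (76430.0 ± 3620.0 against 27870.0 ± 1330.0, adjusted p = 2.61e-06) rose, which quantile normalization did not call (adjusted p = 1). Median, mean and camera direction differed in sign for the P53 target, synapse, glycolysis, matrix and mitochondrial genome lists.

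**Figure D3:**
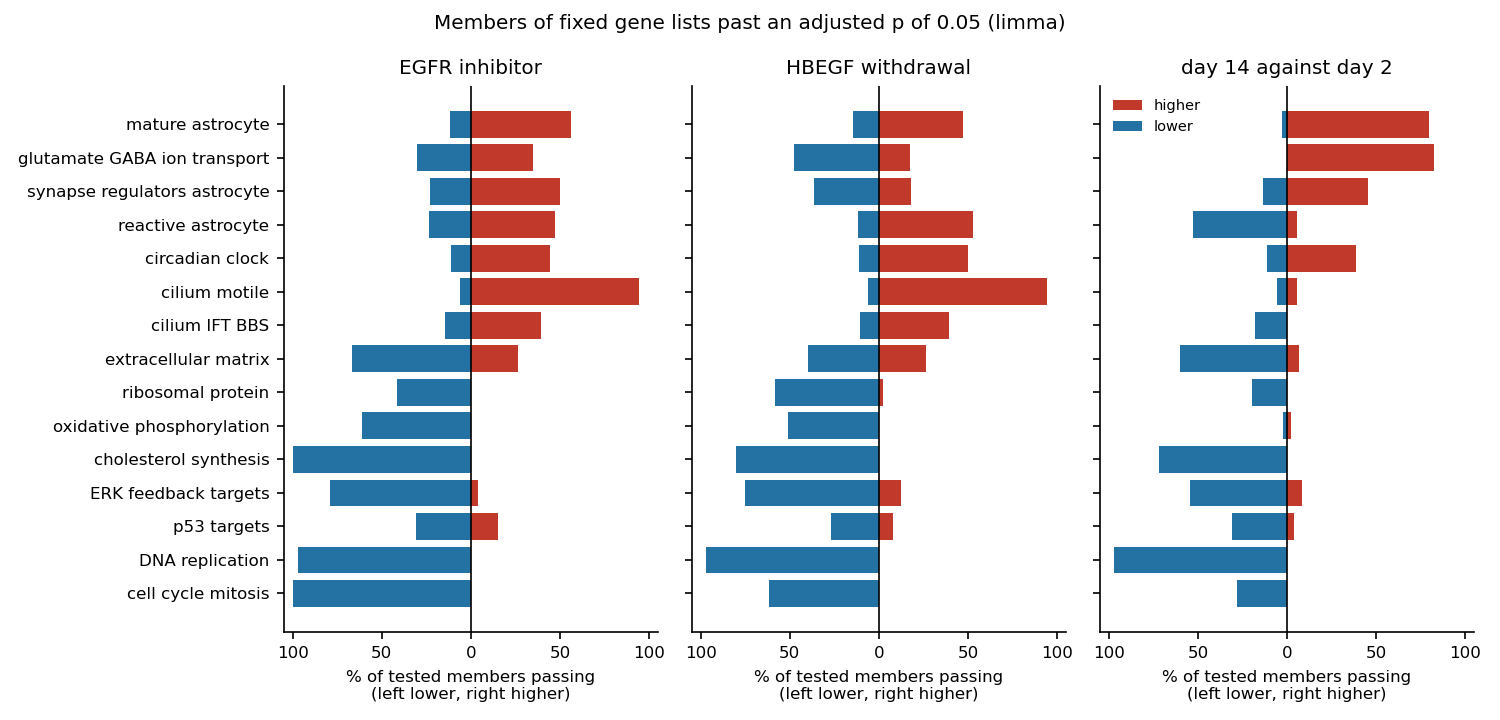
Percent of tested members of fixed gene lists that passed in limma, lower to the left and higher to the right, in 3 comparisons. Motile cilium genes had 16 of 17 higher with the EGFR inhibitor and after HBEGF withdrawal, and DNA replication genes had 34 of 35 lower in all 3.

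EGFR inhibitor and HBEGF withdrawal were compared gene by gene. Changes in the 13850 tested genes had correlations of 0.611 (Pearson, jackknife SE 0.0708 over 10 libraries) and 0.616 (Spearman). In both comparisons 979 genes rose and 2226 fell, against 227 and 693 if the calls were independent. Opposite calls numbered 36 and 9, against 510 and 309. The shared falls depend on scaling, as both totals do (above). The 2261 genes that rose with the inhibitor had a median log2 change of 0.39 after withdrawal (camera p = 5.81e-48, or p = 0.000731 with an estimated correlation). For the 3076 that fell it was -0.61 (camera p = 1.37e-68, or p = 0.000206 with an estimated correlation). Gfap (3.90 ± 0.38 with the inhibitor, 3.55 ± 0.47 after withdrawal), Inka2 (-3.11 ± 0.16, -3.28 ± 0.20), Dusp6 (-3.32 ± 0.31, -3.09 ± 0.38) and Cyp1b1 (3.16 ± 0.28, 3.13 ± 0.34) were among the largest changes in each.

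The change with the inhibitor differed from the change after withdrawal in 253 genes by limma, 176 of them more positive with the inhibitor, and in 108 when HBEGF replicate 1 was left out. The following were chosen after the values were seen. Miat rose more with the inhibitor (3.42 against 1.46 in log2, adjusted p of the difference = 0.00284), as did Entpd2 (2.26 against 1.27, 0.0105). Tppp3 (1.49 against 3.04, 0.000689), Lyz2 (1.14 against 3.95, 0.00146) and Mbp (0.29 against 1.44, 0.0133) had larger changes after withdrawal. Fabp7 fell further after withdrawal (-1.60 against -3.18, 0.00141), and Ccnd1 fell further with the inhibitor (-4.66 against -2.50, 0.0125). Ednrb (1.19 against -0.40, 0.0108) rose with the inhibitor and did not pass after withdrawal (adjusted p = 0.22). Sox11 (0.32 against -0.50, 0.00813) and Myadm (-0.50 against 1.75, 0.000689) changed in opposite directions.

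**Figure D4:**
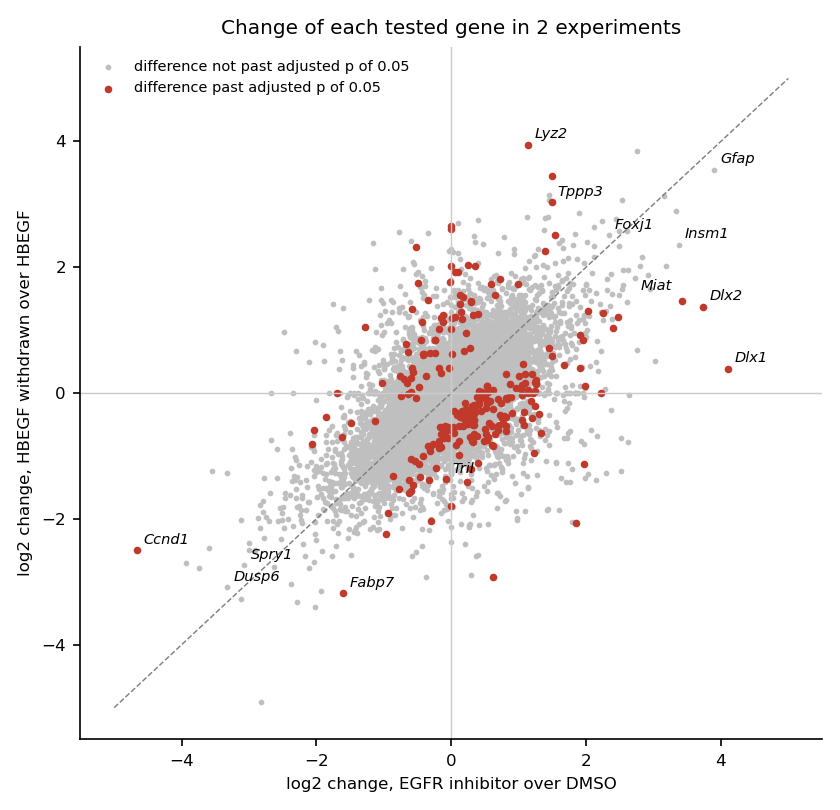
Log2 change of 13850 genes with the EGFR inhibitor (n = 3 against 3) and after HBEGF withdrawal (n = 2 against 2). Before rescaling, 979 genes rose and 2226 fell in both (correlation 0.611).

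The third comparison asked which genes differ with the P53 inhibitor (n = 3) from its DMSO control (n = 3). Txnip, which encodes a thioredoxin binding protein regulated by glucose, fell 4.31-fold, from 13.7 ± 0.941 to 3.18 ± 0.913 RPKM (log2 change -1.84 ± 0.33, adjusted p = 0.0228; ENSMUSG00000038393.14, chromosome 3, 96557957 to 96561883). Its relative Arrdc4 fell too (0.838 ± 0.157 against 2.43 ± 0.131, log2 change -0.90 ± 0.13, adjusted p = 0.00639; chosen after the values were seen). The cyclin kinase inhibitor gene Cdkn1c (2.23 ± 0.234 against 6.35 ± 1.09, log2 change -1.18 ± 0.20, adjusted p = 0.0194) fell. Plekhb1 (3.75 ± 0.117 against 6.58 ± 0.387, adjusted p = 0.0471) and the iron reductase gene Cybrd1 (5.61 ± 0.534 against 9.16 ± 1.06, adjusted p = 0.0194) fell too, and Lynx1 (6.93 ± 0.886 against 3.9 ± 0.567, log2 change 0.69 ± 0.13, adjusted p = 0.0445) rose. By limma 25 of 13850 genes changed, 4 higher and 21 lower, and 1128 had an unadjusted p under 0.05. The other 3 higher genes, chosen after the values were seen, were Acadl (4.37 ± 0.288 against 2.45 ± 0.216, adjusted p = 0.00926), Mir124a-2 and Gm37508, the last 2 listed at 0 with DMSO (adjusted p = 0.0133 and 0.00926). Also chosen in this way among the lower ones were Miat (1.24 ± 0.0848 against 4.42 ± 0.514, adjusted p = 0.00926), Mfsd2a (0.902 ± 0.108 against 2.92 ± 0.145, adjusted p = 0.0169) and Igsf9b (0.661 ± 0.0452 against 2.14 ± 0.258, adjusted p = 0.000599).

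These calls rested on few libraries. Without P53_inhibitor replicate 2 only 2 genes passed, and without P53_DMSO replicate 2 there were 37. Leaving out P53_inhibitor replicate 2 gave adjusted p = 0.164 for Txnip, 0.125 for Cdkn1c, 0.0759 for Cybrd1, 0.209 for Lynx1 and 0.181 for Plekhb1. Transcripts of the P53 pathway itself did not pass with the spread pooled over all groups, which does not show them unchanged. Trp53 (7.07 ± 0.345 against 8.52 ± 1.23, log2 change -0.23 ± 0.12, adjusted p = 0.683) lies on chromosome 11 (ENSMUSG00000059552.13, 69580359 to 69591873). Cdkn1a (24.6 ± 1.6 against 16.3 ± 1.41, log2 change 0.57 ± 0.30, adjusted p = 0.687) lies on chromosome 17 (ENSMUSG00000023067.14, 29090976 to 29100727). Mdm2 (4.8 ± 0.0887 against 4.85 ± 0.34, adjusted p = 1) was the last of these. The cyclin gene Ccng1 (46.1 ± 1.84 against 29.8 ± 1.45, adjusted p = 0.135) did not pass either, although voom gave adjusted p = 0.0324. Neither did Egfr (7.27 ± 0.106 against 7.18 ± 0.289, adjusted p = 1) or Hbegf (1.16 ± 0.0364 against 1.05 ± 0.106, adjusted p = 1). Gfap (1.22 ± 0.116 against 1.16 ± 0.198, adjusted p = 1), Aqp4 (6.59 ± 0.124 against 7.81 ± 0.414, adjusted p = 0.915) and Mki67 (45.1 ± 2.28 against 33.5 ± 3.63, adjusted p = 0.931) did not pass.

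In the lists, 0 members passed over all genes by limma, where 1128 of all genes had an unadjusted p under 0.05, but camera called 10 lists. Higher were P53 targets (median 0.13, camera adjusted p = 0.00880, or adjusted p = 0.628 with an estimated correlation). DNA replication genes were higher (0.18, camera adjusted p = 6.42e-05, or 0.639 with an estimated correlation), as was mitosis (0.23, 0.000529 or 0.728). Also higher were targets of ERK feedback (0.09, camera adjusted p = 0.00288, or adjusted p = 0.628 with an estimated correlation) and glycolysis (0.12, camera adjusted p = 0.000434, or adjusted p = 0.448 with an estimated correlation). The same held for oxidative phosphorylation (0.13, camera adjusted p = 6.42e-05, or adjusted p = 0.628 with an estimated correlation) and the mitochondrial genome (0.23, camera adjusted p = 0.0245, or adjusted p = 0.628 with an estimated correlation). The ERK feedback list did not pass without P53_DMSO replicate 3 (adjusted p = 0.0547), nor did the interferon list without P53_DMSO replicate 2 (0.199). The mitochondrial genome call was lost without P53_DMSO replicate 3 (0.544) or P53_inhibitor replicate 3 (0.106), and with a pseudocount of 0.1 (0.0726), a filter of 5 RPKM (0.116), quantile normalization (0.178), the experiment alone (0.0887) or log2(CPM + 1) (0.0624). Lower were radial glia genes (-0.12, camera adjusted p = 0.000882, or adjusted p = 0.203 with an estimated correlation). Interferon genes (-0.22, camera adjusted p = 0.000576, or adjusted p = 0.475 with an estimated correlation) were lower, and so were oligodendrocyte precursor genes (-0.20, camera adjusted p = 5.86e-05, or adjusted p = 0.203 with an estimated correlation).

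Adjusted over the list alone, 5 of 11 oligodendrocyte precursor genes fell, 3 of 28 radial glia genes fell and 1 of 10 interferon genes fell. Examples that did not pass over all genes were Gpr17 (0.559 ± 0.158 against 4.1 ± 0.585, adjusted p = 0.0730), Sox10 (1.48 ± 0.113 against 4.36 ± 0.851, adjusted p = 0.0898) and Sox4 (10.3 ± 0.657 against 20.1 ± 2.84, adjusted p = 0.0667). Over the list alone 3 of 19 glycolysis, 2 of 41 oxidative phosphorylation, 1 of 24 ERK feedback, 1 of 26 P53 target and 1 of 10 mitochondrial genome genes rose. The other 19 lists were not called by camera (adjusted p from 0.0647 for cholesterol synthesis to 0.953 for microglia). Of them cholesterol genes passed as higher without P53_inhibitor replicate 3 (0.0403) or with voom (0.0212), immediate early genes as higher without P53_inhibitor replicate 1 (0.0489), ribosomal protein genes as lower without P53_DMSO replicate 1 (0.0152) and oligodendrocyte genes as lower with voom (0.00742). Median, mean and camera direction differed in sign for the mature astrocyte, EGF ligand, motile cilium, reactive, stress, matrix and microglia lists.

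The fourth comparison asked which genes differ between day 14 (n = 3) and day 2 in vitro (n = 3). Apoe, which encodes the main lipid carrier of astrocytes, rose 22.5-fold, from 19.3 ± 8.72 to 434 ± 195 RPKM (log2 change 4.39 ± 0.30, adjusted p = 3.8e-08; ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188). Thbd, which encodes the receptor thrombomodulin, fell 30.5-fold, from 5.30 ± 1.48 to 0.174 ± 0.0696 RPKM (log2 change -2.40 ± 0.17, adjusted p = 3.84e-08). Of the fixed groups, 27 of 34 mature astrocyte genes and 19 of 23 ion and transmitter transport genes rose, and 34 of 35 DNA replication genes fell. By limma 3208 genes changed, 769 higher and 2439 lower, with 143 and 215 differing by at least 1 in log2. Median-of-ratios scaling gave 1202 higher and 1140 lower, quantile normalization 1153 and 1204, and leaving out mitochondrial genes 1062 and 1358. Without DIV14 replicate 1 the number was 2080.

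Among the largest increases were the chaperone gene Cryab (17.6 ± 3.35 against 1.57 ± 0.782, adjusted p = 1.01e-06) and Aqp4 (18.9 ± 7.84 against 2.09 ± 1.44, log2 change 2.72 ± 0.27, adjusted p = 2.1e-06). The metallothionein gene Mt2 (78.2 ± 37.4 against 11.3 ± 3.33, adjusted p = 0.000242) and the selenium carrier gene Selenop (11.3 ± 3.88 against 1.17 ± 0.336, adjusted p = 5.31e-08) rose. Tril (80.7 ± 10.8 against 15.3 ± 1.67, adjusted p = 6.18e-10) and the signalling gene Wnt5a (11.6 ± 1.44 against 1.68 ± 0.479, adjusted p = 3e-07) did too. The mitochondrial transfer RNA gene mt-Te rose (41.1 ± 21.2 against 8.37 ± 8.03, adjusted p = 0.0168), but not without DIV14 replicate 1 (0.0718), DIV14 replicate 3 (0.0612) or DIV2 replicate 3 (0.0899). Decreases included Hmga1b (0.972 ± 0.309 against 13.5 ± 8.18, adjusted p = 0.00137) and Tagln2 (5.67 ± 2.38 against 37.4 ± 5.56, adjusted p = 4.49e-06). Lgals1 (12.6 ± 1.84 against 81 ± 30.8, adjusted p = 2.59e-06) and the deiodinase gene Dio2 (2.68 ± 1.33 against 18.9 ± 4.8, adjusted p = 3.97e-06) fell. The matrix gene Tnc (3.1 ± 1.9 against 19.2 ± 5.39, adjusted p = 5.94e-05) and Gng3 (2.07 ± 0.235 against 14 ± 1.51, adjusted p = 8.02e-07) fell as well. Mir8100 fell (8.70 ± 7.51 on day 2, 0.459 ± 0.795 on day 14, adjusted p = 0.0165), but not without DIV14 replicate 1 (0.0699), DIV14 replicate 2 (0.0544) or DIV2 replicate 3 (0.0841).

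Mature astrocyte genes stood at 27 higher and 1 lower of 34 (29 and 1 adjusted over the list alone), median 1.07 (camera adjusted p = 1.52e-25, or adjusted p = 0.0833 with an estimated correlation), among them Mlc1 (15.5 ± 2.77 against 4.17 ± 0.479, adjusted p = 3.84e-08) and the GABA transporter gene Slc6a11 (4.76 ± 1.19 against 1.39 ± 0.161, adjusted p = 3.11e-06). Ion and transmitter transport genes stood at 19 higher and 0 lower of 23 (19 and 2 adjusted over the list alone), median 0.74 (camera adjusted p = 2.07e-18, or adjusted p = 0.00570 with an estimated correlation). P2ry1 (8.53 ± 0.867 against 3.08 ± 0.31, adjusted p = 3.94e-07) rose. Synapse regulating genes stood at 10 higher and 3 lower of 22 (12 and 4 adjusted over the list alone, camera adjusted p = 0.000156, or adjusted p = 0.0833 with an estimated correlation). Vcan (0.679 ± 0.0954 against 2.21 ± 0.0583, adjusted p = 1.99e-07) fell. Clock genes stood at 7 higher and 2 lower of 18 (10 and 2 adjusted over the list alone, camera adjusted p = 0.000202, or adjusted p = 0.0833 with an estimated correlation). Radial glia genes gave 4 higher and 10 lower of 28 (5 and 12 adjusted over the list alone, camera adjusted p = 0.529), or 6 and 6 under median-of-ratios scaling. Cd24a (13.6 ± 1.91 against 41.9 ± 9.06, adjusted p = 1.85e-07) and Sox11 (18.8 ± 1.37 against 31 ± 2.71, adjusted p = 6.02e-05) fell. Reactive astrocyte genes gave 1 higher and 9 lower of 17 (1 and 9 adjusted over the list alone, camera adjusted p = 0.201), and their list passed as lower under median-of-ratios scaling (0.0362) and quantile normalization (0.0213). Cp (2.93 ± 0.534 against 0.368 ± 0.0901, adjusted p = 3.02e-07) rose and Cd44 (0.705 ± 0.0929 against 2.42 ± 0.656, adjusted p = 9.78e-06) fell.

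DNA replication genes stood at 0 higher and 34 lower of 35 (0 and 35 adjusted over the list alone), median -0.78 (camera adjusted p = 1.65e-13, or adjusted p = 0.381 with an estimated correlation). Mitosis genes stood at 0 higher and 11 lower of 39 (0 and 24 adjusted over the list alone, camera adjusted p = 8.43e-05, or adjusted p = 0.757 with an estimated correlation), but only 1 of 39 was lower under median-of-ratios scaling. Mki67 (27.5 ± 7.98 against 54.2 ± 16.2, adjusted p = 0.257) did not pass. Cholesterol synthesis genes stood at 0 higher and 18 lower of 25 (0 and 23 adjusted over the list alone, camera adjusted p = 3.26e-07, or adjusted p = 0.467 with an estimated correlation), but 11 lower under median-of-ratios scaling. Matrix genes stood at 1 higher and 9 lower of 15 (2 and 10 adjusted over the list alone, camera adjusted p = 0.000499, or adjusted p = 0.116 with an estimated correlation). ERK feedback targets stood at 2 higher and 13 lower of 24 (3 and 13 adjusted over the list alone, camera adjusted p = 0.0336, or adjusted p = 0.757 with an estimated correlation). Phlda1 (4.47 ± 0.575 against 21 ± 6.34, adjusted p = 3.48e-06) fell. That list had 4 higher and 9 lower under median-of-ratios scaling and did not pass without DIV2 replicate 1 (adjusted p = 0.0772) or DIV14 replicate 1 (0.172).

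Genes on the mitochondrial genome stood at 8 higher and 0 lower of 10 (9 and 0 adjusted over the list alone, camera adjusted p = 2.59e-09, or adjusted p = 0.0833 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.445). Oxidative phosphorylation genes gave 1 higher and 1 lower of 41 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0347, or adjusted p = 0.757 with an estimated correlation), and 7 higher and 0 lower under median-of-ratios scaling. Without DIV14 replicate 2 (median -0.09, adjusted p = 0.636) or DIV2 replicate 3 (-0.10, 0.933) this list did not pass, and its median of 0.02 changed sign. The call was also lost with no filter (0.0843), a filter of 5 RPKM (0.0677), log2(CPM + 1) (0.102) and voom (0.129). Ribosomal protein genes gave 0 higher and 8 lower of 41 (0 and 3 adjusted over the list alone, camera adjusted p = 0.0358, or adjusted p = 0.757 with an estimated correlation) but 0 and 0 in limma under median-of-ratios scaling. The list did not pass there (adjusted p = 0.137). Neither did it without DIV2 replicate 1 (0.0616), DIV2 replicate 2 (0.696), DIV14 replicate 1 (0.151) or DIV14 replicate 3 (0.263). Glycolysis genes gave 3 higher and 7 lower of 19 (3 and 10 adjusted over the list alone, camera adjusted p = 0.276), or 3 and 4 under median-of-ratios scaling. Aldoc (49.3 ± 15.8 against 21.8 ± 3.04, adjusted p = 0.000271) rose. Stress genes gave 0 higher and 6 lower of 26 (0 and 6 adjusted over the list alone, camera adjusted p = 0.977), with a median of -0.04, or 0.146 under median-of-ratios scaling.

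The other 17 lists were not called by camera between days 2 and 14 (adjusted p from 0.0590 for interferon to 0.977 for microglia). Of them interferon genes passed as higher without DIV14 replicate 2 (0.0362) or with voom (0.0156), and with voom radial glia (0.0156) and cytoskeleton genes (0.038) passed as lower. P53 targets gave 1 higher and 8 lower of 26 (1 and 8 adjusted over the list alone, camera adjusted p = 0.728), or 2 and 3 under median-of-ratios scaling. Markers of neurons gave 2 higher and 2 lower of 11 (2 and 2 adjusted over the list alone, camera adjusted p = 0.702). Nefl (0.0871 ± 0.0735 against 2.04 ± 0.634, adjusted p = 5.07e-05) fell. Median, mean and camera direction differed in sign for the motile cilium, intraflagellar transport, stress, BMP and Notch, and oligodendrocyte lists.

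Of the genes set in advance, Trp53 (6.94 ± 1.26 against 12.8 ± 1.72, log2 change -0.80 ± 0.12, adjusted p = 0.000169) fell. Egfr (7.24 ± 1.37 against 4.76 ± 1.35, log2 change 0.53 ± 0.16, adjusted p = 0.0208) rose, but not without DIV14 replicate 1 (adjusted p = 0.127), DIV2 replicate 1 (0.0864) or DIV2 replicate 2 (0.107). Cdkn1a (15.7 ± 7.58 against 29.5 ± 7.86, log2 change -0.96 ± 0.30, adjusted p = 0.0293) fell. It did not pass under median-of-ratios scaling (adjusted p = 0.0858) or without DIV2 replicate 1 (0.101), DIV14 replicate 1 (0.203) or DIV2 replicate 2 (0.111). Mdm2 (5.45 ± 0.736 against 7.29 ± 0.863, adjusted p = 0.0218) fell, but not under median-of-ratios scaling (0.243) or without DIV14 replicate 1 (0.125) or DIV2 replicate 2 (0.117). Hbegf (3.92 ± 1.03 against 10.4 ± 4.53, adjusted p = 0.0920) did not pass, except without DIV2 replicate 3 (adjusted p = 0.0361), and neither did Gfap (4.87 ± 4.21 against 2.22 ± 0.947, adjusted p = 0.223). Hbegf lies on chromosome 18 (ENSMUSG00000024486.6, 36504927 to 36515805).

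The steps within the time course were asked separately. From day 2 to day 7, 1899 genes changed by limma, 571 higher and 1328 lower, or 666 and 763 under median-of-ratios scaling, and 938 without DIV2 replicate 2. Apoe rose to 195 ± 36.3 RPKM (3.33 ± 0.30, adjusted p = 1.91e-06) and Aqp4 to 9.59 ± 2.75 (1.84 ± 0.27, adjusted p = 0.000246). Mature astrocyte genes stood at 22 higher and 1 lower of 34 (23 and 1 adjusted over the list alone, camera adjusted p = 4.49e-19, or adjusted p = 0.157 with an estimated correlation). Ion and transmitter transport genes stood at 15 higher and 0 lower of 23 (15 and 0 adjusted over the list alone, camera adjusted p = 2.93e-14, or adjusted p = 0.0193 with an estimated correlation). Mitosis genes stood at 0 higher and 21 lower of 39 (0 and 39 adjusted over the list alone, camera adjusted p = 7.1e-13, or adjusted p = 0.433 with an estimated correlation). DNA replication genes stood at 0 higher and 26 lower of 35 (0 and 33 adjusted over the list alone, camera adjusted p = 3.46e-14, or adjusted p = 0.433 with an estimated correlation) and matrix genes at 0 higher and 8 lower of 15 (0 and 11 adjusted over the list alone, camera adjusted p = 7.62e-07, or adjusted p = 0.0452 with an estimated correlation). Under median-of-ratios scaling 12 mitosis and 16 DNA replication genes were lower. Mki67 (25.7 ± 18.5 against 54.2 ± 16.2, adjusted p = 0.0967) did not pass, with DIV7 replicate 3 at 4.41 RPKM.

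Also lower from day 2 to day 7 were the lists for cholesterol synthesis (0 higher and 9 lower of 25, or 5 lower under median-of-ratios scaling, camera adjusted p = 3.2e-06, or adjusted p = 0.433 with an estimated correlation), reactive astrocytes (1 higher and 7 lower of 17, camera adjusted p = 0.0223, or adjusted p = 0.433 with an estimated correlation) and glycolysis (2 higher and 7 lower of 19, camera adjusted p = 0.0259, or adjusted p = 0.433 with an estimated correlation). Higher were those for synapses (10 higher and 3 lower of 22, camera adjusted p = 0.00281, or adjusted p = 0.199 with an estimated correlation) and the mitochondrial genome (3 higher and 0 lower of 10, camera adjusted p = 0.00340, or adjusted p = 0.433 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.873), with a pseudocount of 0.1 (0.074), no filter (0.117) or the experiment alone (0.0812), and without DIV2 replicate 2 (0.109). Reactive astrocyte genes did not pass without DIV2 replicate 1 (adjusted p = 0.0745) or DIV7 replicate 2 (0.0889), with a replicate block (0.0535) or fitted alone (0.0671), and with a filter of 5 RPKM their direction turned (median 0.10, adjusted p = 0.788). Glycolysis did not without DIV2 replicate 1 (0.0639), DIV7 replicate 1 (0.0566) or DIV7 replicate 2 (0.0889), with a filter of 5 RPKM (0.128) or fitted alone (0.0671). Of the genes set in advance, Trp53 (9.07 ± 0.635 against 12.8 ± 1.72, adjusted p = 0.0216), Cdkn1a (14 ± 3.12 against 29.5 ± 7.86, adjusted p = 0.0340) and Mdm2 (5.19 ± 0.443 against 7.29 ± 0.863, adjusted p = 0.0166) fell, and Egfr (6.65 ± 1.53 against 4.76 ± 1.35, adjusted p = 0.0931), Hbegf (4.11 ± 2.9 against 10.4 ± 4.53, adjusted p = 0.101) and Gfap (2.36 ± 1.75 against 2.22 ± 0.947, adjusted p = 0.984) did not pass.

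From day 7 to day 14 only 19 genes passed by limma, 7 higher and 12 lower, or 15 and 3 under median-of-ratios scaling, 1483 had an unadjusted p under 0.05, and 0 passed without DIV14 replicate 2. Chosen after the values were seen, Mlc1 (15.5 ± 2.77 against 9.48 ± 1.57, adjusted p = 0.0391) and Selenop (11.3 ± 3.88 against 4.96 ± 0.799, adjusted p = 0.0391) rose, and Sox11 (18.8 ± 1.37 against 28.1 ± 4.16, adjusted p = 0.0391), Cd24a (13.6 ± 1.91 against 22.2 ± 1.68, adjusted p = 0.0400) and Rlbp1 (1.79 ± 0.61 against 4.68 ± 0.739, adjusted p = 0.0391) fell. Camera called 11 lists, but limma passed only 1 mature astrocyte and 2 radial glia genes among their members. Mature astrocyte (0.28, camera adjusted p = 4.56e-10, or 0.302 with an estimated correlation) and ion and transmitter transport genes (0.18, 3.64e-07 or 0.0738) were higher. Clock (0.09, camera adjusted p = 2.67e-05, or 0.0738 with an estimated correlation) and motile cilium genes (0.12, 8.32e-05 or 0.116) were called higher. Mitochondrial genome genes (0.43, camera adjusted p = 4.56e-10, or adjusted p = 0.0738 with an estimated correlation) were higher. Those calls for motile cilium and mitochondrial genome genes were lost under quantile normalization (adjusted p = 0.0651 and 0.0844). Mitosis genes were called higher (0.26, camera adjusted p = 8.04e-06, or adjusted p = 0.598 with an estimated correlation), but lower without DIV7 replicate 3 (median -0.29, adjusted p = 0.00271), the library with Mki67 at 4.41 RPKM, so no direction is given for them. Radial glia (-0.26, camera adjusted p = 0.000229, or adjusted p = 0.0738 with an estimated correlation) and ribosomal protein genes (-0.28, camera adjusted p = 3.64e-07, or adjusted p = 0.566 with an estimated correlation) were lower. Oligodendrocyte precursor (-0.20, camera adjusted p = 0.00338, or adjusted p = 0.260 with an estimated correlation) and cholesterol genes (-0.17, camera adjusted p = 0.0260, or adjusted p = 0.649 with an estimated correlation) were lower. DNA replication genes (-0.17, camera adjusted p = 0.0495, or adjusted p = 0.747 with an estimated correlation) were lower too. Oligodendrocyte precursor genes did not pass without DIV14 replicate 3 (adjusted p = 0.0981). Without DIV7 replicate 1, DIV7 replicate 2 or DIV14 replicate 1, neither cholesterol (0.471, 0.457 and 0.621) nor DNA replication genes (0.895, 0.57 and 0.239) passed.

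The last comparison asked how genes that change over days in culture behave under the treatments. Of 143 genes that rose by at least 1 in log2 from day 2 to day 14, 78 rose and 15 fell with the EGFR inhibitor, with a median log2 change of 0.63 (camera adjusted p = 4.07e-11, or adjusted p = 0.158 with an estimated correlation). After HBEGF withdrawal 62 rose and 17 fell, with a median of 0.54, or 0.15 without DIV14 replicate 1 (camera adjusted p = 1.86e-08, or adjusted p = 0.171 with an estimated correlation). Of 215 genes that fell over the days, 15 rose and 119 fell with the EGFR inhibitor, with a median of -0.77 (camera adjusted p = 7.91e-11, or adjusted p = 0.0854 with an estimated correlation). After withdrawal 13 rose and 94 fell, with a median of -0.59, or -0.94 without DIV14 replicate 3 and -0.29 under median-of-ratios scaling (camera adjusted p = 7.61e-05, or adjusted p = 0.171 with an estimated correlation). With the P53 inhibitor the medians were -0.09 (camera adjusted p = 0.00254, or adjusted p = 0.371 with an estimated correlation) and 0.11 (0.000719, or adjusted p = 0.211 with an estimated correlation), with 0 rising and 3 falling of the 143 and 0 changed of the 215 by limma. They were -0.14 without DIV14 replicate 1 and 0.06 without P53_inhibitor replicate 2. Apoe was at 520.3 ± 16.7 RPKM with the EGFR inhibitor against 105.2 ± 15.7 (2.31 ± 0.30, adjusted p = 1.02e-05) and rose by 1.82 ± 0.36 in log2 after withdrawal (adjusted p = 0.000864). Across all genes the changes from day 2 to day 14 had a correlation of 0.366 with those of the EGFR inhibitor, 0.298 with those of withdrawal and -0.112 with those of the P53 inhibitor.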

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

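Calls in the order EGFR inhibitor, HBEGF withdrawal, P53 inhibitor, days 14 against 2, 7 against 2 and 14 against 7 were 5337, 4511, 25, 3208, 1899 and 19, and 253 genes differed between the first 2 treatments. Under median-of-ratios scaling the larger direction changed from lower to higher for the EGFR inhibitor (2971 higher and 2457 lower), HBEGF withdrawal (2296 and 1798), day 14 against 2 (1202 and 1140) and day 14 against 7 (15 and 3). From day 7 to 14 the mitosis list reversed without DIV7 replicate 3 (adjusted p = 0.00271), and the stress list passed as higher without DIV14 replicate 1 (0.0198). Camera's direction alone turned for the DNA replication list without DIV7 replicate 2 (median -0.0373, 0.57) or DIV14 replicate 1 (-0.00227, 0.239). From day 2 to 7 it turned for the reactive list with a filter of 5 RPKM (0.788) and the mitochondrial genome list under quantile normalization (0.873). Where a value moved, the cause was not tested.

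A filter of 5 RPKM gave 2069, 1882, 8, 1267 and 825 calls for the first 5 comparisons, 100 genes for the difference and 7 lists for HBEGF withdrawal. No filter gave 44 calls for day 14 against 7, 696 for the difference and 21 withdrawal lists. The filter of 5 RPKM lost the withdrawal calls of ERK feedback (adjusted p = 0.0729) and clock genes (0.177) and the day 14 against 2 calls of ERK feedback (0.583) and matrix genes (0.535). With a pseudocount of 0.1 the correlation between the EGFR inhibitor and withdrawal was 0.458.

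Of the settings added after the data were seen, leaving out mitochondrial genes gave 4184 calls for withdrawal and 2420 for day 14 against 2. With log2(CPM + 1) there were 8565, 7124, 94, 4998, 3151 and 148, with 765 for the difference, 20 withdrawal lists and a correlation of 0.746. With voom there were 8584, 6940, 114, 5037, 2901 and 97, with 655 for the difference and 21 withdrawal lists.

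With each experiment fitted alone limma gave 0 calls for HBEGF withdrawal (3926 at unadjusted p under 0.05; voom in the shared fit gave 6940), 1287 for day 14 against 2, 190 for day 7 against 2, 0 for day 14 against 7 (938 unadjusted; voom 97), 45 for the difference and 16 lists for the P53 inhibitor. Array weights gave 334 for the P53 inhibitor. A replicate block gave 6 for the P53 inhibitor, 7 for day 14 against 7 and 63 for the difference, while 7 of 17 libraries correlated best with their own replicate number (-0.0951 to 0.118), so the numbers need not be pairs.

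With an estimated correlation camera called 1, 2, 0 and 1 lists for the EGFR inhibitor, withdrawal, P53 inhibitor and day 14 against 2, where the P53 inhibitor lists numbered 10 by the preset and 2 by fry. Culture-day genes, rising then falling, had medians of 0.634 and -0.768 with the EGFR inhibitor (adjusted p = 0.158 and 0.0854 by camera with an estimated correlation), 0.538 and -0.586 after withdrawal (0.171 and 0.171) and -0.0870 and 0.108 with the P53 inhibitor (0.371 and 0.211, or 0.232 and 0.283 by fry). Fry called 20 lists for the EGFR inhibitor.

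Leaving out each library gave 4565 to 4823 calls for the EGFR inhibitor, 3165 to 3853 for withdrawal, 2 (without P53_inhibitor replicate 2) to 37 for the P53 inhibitor, 2080 (without DIV14 replicate 1) to 2995 for day 14 against 2, 938 (without DIV2 replicate 2) to 1691 for day 7 against 2, 0 (without DIV14 replicate 2) to 19 for day 14 against 7, and 108 (without HBEGF replicate 1) to 220 for the difference. Lists numbered 13, 14 to 15, 8 to 11 and 10 to 12. The culture-day medians ran from 0.472 to 0.742, -1.01 to -0.526, 0.152 to 0.578, -0.936 to -0.436, -0.143 to -0.0705 and 0.0596 to 0.125, and the correlation from 0.535 to 0.603. A lone HBEGF or withdrawal library was assumed to vary like the other groups. Depth of 4009173 to 9690782 reads limits calls to genes with enough reads.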

Other observations

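The tests in this section were chosen after the results were seen, except those with thinned reads, which were written before. Summed CPM of 22 endothelial genes were 2.49-fold higher after withdrawal and 1.91-fold with the inhibitor.

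More genes fell than rose with the EGFR inhibitor, after HBEGF withdrawal and by day 14 (42.4, 30.8 and 24.0% of called genes higher). The larger share of mitochondrial RNA could produce this by taking reads from all other genes: without mitochondrial genes the percentages were 49.36, 48.45 and 43.88, and 48.97 to 50.26, 45.89 to 52.24 and 42.52 to 48.38 with each library left out. Any rescaling of whole libraries moves this share (54.73, 56.08 and 51.32% under median-of-ratios scaling), and without mitochondrial genes the medians at 5 RPKM or more were still -0.25, -0.26 and -0.07, so it stays open. Differences in depth might act likewise, but thinning every library to the depth of the smallest gave 41.77, 30.0 and 24.01%, which argues against depth. Whether cells truly held more mitochondrial RNA or lost other RNA was not tested.

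Dlx1 and Dlx2 rose by 157.7 CPM in sum with the EGFR inhibitor, to 159.1 ± 10.6. Mature neurons left by HepaCAM immunopanning could add them. Snap25, Syt1, Stmn2, Syn1, Nefl and Nefm summed to 49.49 ± 7.26 CPM against 62.42 ± 8.88 with DMSO. That argues only against neurons rich in these genes. The neuron list as a whole (30 genes) went the other way, at 1444 ± 34.2 CPM against 821 ± 32.7. Immature neurons may be the source. Of 26 other detected neuron genes 14 (53.85%) were higher in each inhibitor than each DMSO library (5% if no gene changed, but 5337 did). Of the 26, 2 were lower, 0 are in another list and 2 had a DMSO mean of 1 RPKM or more, which leaves it open. Dlx1 did not pass after HBEGF withdrawal (log2 change 0.39, adjusted p = 0.691) while Dlx2 rose (1.37, adjusted p = 0.0251), and Dlx1 was at 5.563 RPKM in HBEGF replicate 1 and 5.521 in DIV7 replicate 3. Astrocytes might themselves switch on these genes when EGFR is blocked, which these values leave open.

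The microglia and oligodendrocyte lists were higher after HBEGF withdrawal. Microglia left by immunopanning could explain the first. Of 23 detected microglia genes 22 (95.65%) were higher in each withdrawal library (16.7% if no gene changed, but 4511 did). That restates the list's call. Of the 23, 1 is in another list and 2 had an HBEGF mean of 1 RPKM or more, so it stays open. Lyz2 and Cd68 rose, but Tmem119 was listed at 0 and Csf1r at 0.0708 ± 0.0268 RPKM. A lower astrocyte share might raise every other type alike. Summed CPM changed 11.88-fold for microglia (8.68 to 15.3 over library pairs), 2.62-fold for oligodendrocytes (1.83 to 4.31) and 0.989-fold for neurons (0.897 to 1.09). Astrocyte RNA in these sums could hide a rise, so this stays open. Whether withdrawal let such cells survive was not tested.

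Each 3 against 3 comparison was also tested against the other splits of its 6 libraries, and the 10 splits are too few for a share under 0.05. The real split gave 5337 calls for the EGFR inhibitor (1 split as large, highest other 1), 25 for the P53 inhibitor (1, highest other 1), 3208 for day 14 against 2 (1, 49), 1899 for day 7 against 2 (1, 1) and 19 for day 14 against 7 (2, 35).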
